A study of Gallus gallus with 4 samples.

How the data were processed

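The data were 4 RNA libraries of chick retinal cells, ThrbPos and ThrbNeg with 2 replicates each. They were taken as droplet single-cell libraries, since the sample titles name single-cell RNA sequencing and the deposited matrix holds UMI counts per cell. The sample records instead describe total RNA taken with a Direct-zol kit and a NEBNext Ultra library kit, as for bulk RNA, and this conflict was not resolved. The submitters' processing notes name Cell Ranger 3.0.0, Seurat 3.1.5 and the build galGal5 without giving their roles, and the gene model is that of Gallus_gallus-5.0 with EGFP and MCHERRY added. The authors merged the libraries into 1 deposited matrix of raw UMI counts, with 19263 features and 18691 cells and 34756187 UMIs in all, and a deposited cell table gives the label, the batch (replicate number) and the counts of UMIs and genes per cell. In 100% of cells the matrix sum equalled the deposited count, and the largest value was 3526. The shares of mitochondrial and ribosomal UMIs and a quality score whose meaning is not given are each a fraction in the deposited cell table. Other columns, per the file headers, are labels, row numbers or gene positions. The deposited cells were already filtered by the authors, and no further cells were left out of the planned comparisons. Of the features, 11783 had a symbol and 7480 an Ensembl identifier only, which was left unnamed. The reference table of a later build shared 0 identifiers with the matrix and was not used.

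Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, scanpy 1.11.5 and matplotlib 3.10.9 was used for clustering, sums and plots, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 for the tests. Clustering used 2000 variable genes seen in at least 20 cells, 30 principal components, 15 neighbours, a graph of shared neighbours and Leiden modularity at resolution 1, with resolutions 0.5 and 2 as alternatives. MCHERRY, EGFP and the W-linked and mitochondrial genes were kept out of the variable genes, and so were HINTW and GSTM2, these last after a first clustering was seen to split on them. Resolution 1 gave 25 clusters, the lower resolution 14 and the higher 33, and 89.6% and 98.3% of cells kept their class. Cell type markers were counted among each cluster's 10 leading genes seen in at least 10% of cells, with 5 added to CPM before folds. Not every name followed from these counts. Of the clusters named progenitor-like, 3 and 4 had tied lists and 9 and 16 held no marker. Cluster 11, named horizontal cell-like, tied horizontal and amacrine cell markers at 3 each, as did cluster 2, which stayed a number. Clusters 7, 8 and 21 stayed numbers though 1 list led there. Other clusters with a tie or no marker stayed numbers. The 15 marker lists were those of progenitor, neurogenic progenitor, photoreceptor, horizontal, ganglion, amacrine and bipolar cells, Mueller glia, ciliary margin, pigment epithelium, lens, erythroid, immune, endothelial or mural and mesenchymal cells. No cluster was named for any of the last 10 of these lists, from amacrine cells on.

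Gene lists, named-gene rules, tests and the first set of alternatives were fixed before the data were examined. Counts were summed per library, filtered by filterByExpr and scaled by TMM. They were tested with edgeR's quasi-likelihood test with group as the only term, at a Benjamini-Hochberg adjusted p of 0.05. CPM values are on the TMM scale. The common dispersion was 0.127 with 2 residual degrees of freedom, and 0.0350 with 1 when the replicate was a block. The batch in the cell table is shared by ThrbPos and ThrbNeg libraries of a number, so the number was taken as a pairing before calls were compared. As a check, over 11793 genes the deviations of same-numbered libraries from their group means correlated at 0.556 across genes, which are not independent replicates. With 2 libraries per group the other pairing gives the same value with its sign turned. The check shows only that same-numbered libraries deviate alike, from whatever cause, and cannot establish the pairing. The same test was run within each class with at least 20 cells in every library, and differences between classes were tested as an interaction with the library as a block. Class shares were tested with edgeR on cell numbers with the library total as offset. The 17 gene lists of the results were tested with camera at a preset correlation of 0.01 where at least 5 members were tested. Alternatives were camera with an estimated correlation and fry.

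For the shares of cells with OTX2 and ONECUT1 each cell was thinned to 1000 UMIs. The planned depth was to keep 80% of the cells of every library, which no planned depth did. Of the 4 libraries, ThrbPos replicate 1 kept 60.6% and ThrbNeg replicate 1 kept 79.2%, so the smallest planned depth was used. Thinned counts were then summed per library and detection class (both, OTX2 only, ONECUT1 only, neither). Shares have 95% Clopper-Pearson intervals from scipy, and a count of 0 was given the limit of 3 counts of the total unless an interval is named. With 2 against 2 libraries, no two-sided exact permutation test can go below p = 0.33, and counts over other splits of the samples were not made, since these need at least 3 libraries per group.

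Genes named in the text were the transgenes, THRB, OTX2 and ONECUT1, and the 10 largest rises and falls (5 within a class or contrast) among called genes with a symbol, a mean log2 CPM of at least 4 and the ThrbPos libraries beyond the ThrbNeg libraries, with up to 4 called members of each list. In contrasts between detection classes the same way in all 4 libraries was asked instead. Genes of the blocked fit were named by the same rule after both fits had been seen. CRX, ISL1, PROX1 and PDE6C were named after their values were seen, and so were the leading genes of clusters. Some genes that the rule names are not reported here.

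Alternatives were DESeq2's size factors and its Wald test, no filter on low counts, the replicate block, leaving out each library, removal of doublets, thinning, the same number of cells from each class with at least 20 cells in every library, TMM on cell numbers and other resolutions. Scrublet, as run in scanpy, marked 20 cells (0.107%), under the 0.5% below which it was taken not to have worked, so leaving out the top 5% of doublet scores per library was added. Also added after the data were seen were keeping cells of at least 1000 UMIs, leaving out clusters 7, 8 and 21, keeping all cells of the classes used for the equal draw, clustering without listed genes (20 clusters, 90.8% of cells in the same class) and photoreceptor-like cells alone. No cluster of a non-retinal type was found, so leaving these out gave no value. For gene lists the measure compared between settings was first the direction of the set test, and was replaced by the list's mean minus that of the other genes after the lists that turned had been seen. Both are reported.

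The tests were tried on simulated counts with 200 changed genes, 6 draws each. With batch effects and spread as in the blocked fit, the group-only test called 0 genes and the blocked test recovered 32.8% of 2-fold and 84.8% of 4-fold changes with 7.71% of calls false. With no batch effect and the spread of the group-only fit, the group-only test recovered 0.667% and 26.5% with 27.2% false, and the blocked test 3.67% and 47.2% with 42.9% false. With nothing changed in that second case the blocked test still called 35.7 genes on average and the group-only test 1.67, and in the first case the blocked test called 3.17. The interaction test recovered 9.83% and 60.3% with 1.64% false at its own spread, and 0.833% and 14.8% with 65.3% false at the spread between libraries within a class, where it called 23.3 genes with nothing changed. The detection test recovered 76% and 95% with 8 of 179 calls false. For the lists, raising the Notch pathway 1.5-fold gave a call for it and for 0 of the 16 others.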

Results

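RNA of single chick (Gallus gallus) retinal cells was counted in 4 libraries, taken to be droplet libraries, 2 with the label ThrbPos and 2 with the label ThrbNeg. Thrb is the gene of thyroid hormone receptor beta, a nuclear receptor found in cone photoreceptors, and the series title names the transcription factors Onecut1 and Otx2 together with early genes of cones and horizontal cells, the interneurons next to the photoreceptors. How cells came by either label is not given in the sources used here. ThrbPos replicate 1 held 1146 cells and 1545362 UMIs (unique molecular identifiers, 1 per counted RNA molecule), and ThrbPos replicate 2 held 9686 cells and 16816442 UMIs. ThrbNeg replicate 1 held 3157 cells and 6559987 UMIs, and ThrbNeg replicate 2 held 4702 cells and 9834396 UMIs. The median cell had 1273, 1634, 1844 and 1931.5 UMIs in that order. The deposited cell table gives the replicate number as a batch that both labels share, so values from a fit with this batch as a block stand beside those of the planned fit, which has the group alone. Nothing in the labels says that the libraries came from separate cultures or animals, so the p-values measure only the spread between these 4 libraries. Intervals on shares are exact Clopper-Pearson 95% intervals and, like the limits beside a count of 0, cover counting error only. Coordinates are those of the build galGal5.

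The first comparison asked which genes differed between all ThrbPos and all ThrbNeg cells. The 2 transgene features and the 3 genes named by the labels or the series title were read first, as CPM (a gene's UMIs over the library total, scaled by TMM factors), with n = 2 libraries per group. THRB (chromosome 2, 37403149 to 37554300) stood at 121 ± 30.5 CPM (SD) in ThrbPos and 8.73 ± 5.61 CPM in ThrbNeg. OTX2 (chromosome 5, 55922636 to 55929314), a homeobox factor of photoreceptor precursors, stood at 1114 ± 106 and 266 ± 6.77 CPM. ONECUT1 (chromosome 10, 8640075 to 8652609), a factor of horizontal cell precursors, stood at 636 ± 178 and 148 ± 6.14 CPM. The green fluorescent protein gene EGFP stood at 144 ± 14.3 and 4.61 ± 6.53 CPM, with 0 UMIs in ThrbNeg replicate 2, which allows up to 0.305 CPM there. The red fluorescent protein gene MCHERRY was high on both sides, at 24041 ± 7612 and 9001 ± 4164 CPM. None of these 5 passed edgeR's quasi-likelihood test with group alone, the Benjamini-Hochberg adjusted p being 0.0698 for THRB, 0.0542 for OTX2, 0.0668 for ONECUT1, 0.236 for EGFP and 0.256 for MCHERRY. With the replicate block all 5 passed the same edgeR quasi-likelihood test, at Benjamini-Hochberg adjusted p = 6.38e-06, 0.000272, 0.000352, 0.000686 and 0.00422 in that order. Within replicate 1 and replicate 2 the log2 fold change was 4.31 and 3.46 for THRB, 2.19 and 1.94 for OTX2, 2.41 and 1.75 for ONECUT1, and 1.62 and 1.3 for MCHERRY.

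Over all cells, 5 of 11793 genes rose in ThrbPos. RCVRN (an unplaced scaffold, 511 to 897), the gene of the photoreceptor calcium sensor recoverin, rose from 1.94 ± 0.0810 CPM to 83.2 ± 33.9 CPM, a log2 fold change of 5.40 (SE 0.40). NANOS1 (chromosome 6, 29993320 to 29994084), which encodes an RNA-binding protein, rose from 2.51 ± 0.512 to 44.2 ± 0.846 CPM (log2 fold change 4.12, SE 0.30). RXRG (chromosome 8, 5154111 to 5168109), a nuclear receptor of cones that pairs with thyroid hormone receptors, rose from 48.3 ± 4.54 to 715 ± 56.2 CPM (log2 fold change 3.89, SE 0.22). RBP4 (chromosome Z, 53526993 to 53532383), a retinol carrier, rose from 455 ± 64.5 to 5726 ± 186 CPM (log2 fold change 3.65, SE 0.25). IMPG2 (chromosome 1, 85206272 to 85256440), a proteoglycan of the matrix around photoreceptors, rose from 12.9 ± 1.37 to 118 ± 6.24 CPM (log2 fold change 3.20, SE 0.22). Each of these means is over n = 2 libraries, and within replicates 1 and 2 the log2 fold changes were 5.59 and 4.81 for RCVRN, 4.2 and 3.86 for NANOS1, 4.06 and 3.71 for RXRG, 3.84 and 3.48 for RBP4, and 3.01 and 3.34 for IMPG2. All 5 had a Benjamini-Hochberg adjusted p of 0.0362 in edgeR's quasi-likelihood test, and 0 genes were lower. At an unadjusted p under 0.05 the same edgeR test counted 1514 genes, and DESeq2's Wald test called 249 higher and 210 lower after adjustment. The count of 5 was fragile: it became 88 without ThrbPos replicate 1, 127 without ThrbNeg replicate 1, 0 without ThrbNeg replicate 2, and 0 without clusters 7, 8 and 21, whose cells held few UMIs for their library. It was also 0 over all cells of the 7 classes and clusters that had at least 20 cells in every library (progenitor-like, photoreceptor-like, horizontal cell-like and clusters 2, 7, 8 and 14), and 0 when every library gave the same number of cells from each of these 7 (equal numbers of cells per class). Neurogenic progenitor-like and ganglion cell-like cells were not among the 7. The median log2 fold change of the 5 genes was 3.98 without ThrbNeg replicate 2, 3.92 without clusters 7, 8 and 21, 3.45 over all cells of the 7 classes and 1.49 with equal numbers of cells per class.

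With the replicate block, 713 genes were higher and 621 lower in ThrbPos. This fit has 1 residual degree of freedom. On simulated counts 7.71% of its calls were false with batch effects and spread as in the blocked fit. With no batch effect and the spread of the group-only fit, 42.9% were. The genes named here from that fit were chosen by the planned rule, but after the values of both fits had been seen. The largest rises with a gene symbol included, besides EGFP, RCVRN, NANOS1, RXRG, THRB and RBP4, the photoreceptor genes SAMD7 (log2 fold change 4.22), NR2E3 (3.71), FSCN2 (3.43) and GNGT2 (3.27), the last encoding a subunit of the cone transducin. The largest falls were NRN1 (−2.73), the peripheral myelin protein gene PMP22 (−2.72), the ganglion cell factor EBF3 (−2.44), the progenitor factor NR2E1 (−2.43), the glial glutamate transporter SLC1A3 (−2.38), the lactate transporter SLC16A1 (−2.34), ISLR2 (−2.30), S100A13 (−2.29), the collagen gene COL5A1 (−2.28) and ANGPTL1 (−2.26). All of these lay on the same side in both replicates, and their Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test with the block ran from 1.21e-06 for RCVRN to 0.00161 for ISLR2.

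Among the gene lists fixed before the data were examined, early cone genes stood highest in ThrbPos. Their median log2 fold change was 3.15 over 12 tested members, 3.33 within replicate 1 and 2.18 within replicate 2, and 1.51 with equal numbers of cells per class. In the fit with group alone 2 of the 12, RCVRN and RXRG, rose, while 11 were higher when adjusted over the list alone and 11 rose with the block, among them the homeobox gene CRX, the differentiation factor NEUROD1 (blocked log2 fold change 2.48) and the phosphodiesterase subunit PDE6H (5.50). PDE6C, another phosphodiesterase subunit, passed in neither and had a log2 fold change of 0.04. As a set the list was higher (camera, Benjamini-Hochberg adjusted p = 1.39e-34, and adjusted p = 0.186 with an estimated correlation).

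Early horizontal cell genes had a median log2 fold change of 1.76 over 12 tested members, 1.80 and 1.33 within replicates 1 and 2, and 0.11 with equal numbers of cells per class. None of the 12 passed with group alone, 8 were higher and 1 lower when adjusted over the list alone, and with the block 8 rose and 2 fell. The block's rises included ONECUT3 (2.96), LHX1 (2.59) and TFAP2A (2.18), all transcription factors, while ISL1 (−1.23) and PROX1 (−0.80) were the pair that fell. The set was higher by camera (Benjamini-Hochberg adjusted p = 2.75e-09, and adjusted p = 0.244 with an estimated correlation). Amacrine cell genes, which share TFAP2A, TFAP2B and PTF1A with the horizontal cell list, had a median of 1.15 over 8 members, with 4 higher and 1 lower when adjusted over the list alone and 4 and 1 with the block. That set was also higher (camera, Benjamini-Hochberg adjusted p = 3.84e-06, and adjusted p = 0.186 with an estimated correlation). Within replicates 1 and 2 its median was 1.59 and 0.80, and with equal numbers of cells per class 0.33.

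Ganglion cell genes lay lower in ThrbPos, with a median log2 fold change of −1.05 over 14 members, −1.56 and −0.75 within replicates 1 and 2. Without ganglion cell-like cells, which the 7 classes leave out, it was −0.021 over all their cells and −0.26 with equal numbers of cells per class. Adjusted over the list alone 2 were higher and 5 lower, and with the block 7 fell, among them NRN1, EBF3, RBPMS2 (−1.92) and the growth cone protein gene GAP43 (−1.57), and the neurofilament gene NEFL rose (1.02). Multipotent progenitor genes had a median of −1.43 over 16 members, −1.90 and −1.19 within replicates 1 and 2, and −0.65 with equal numbers of cells per class. Adjusted over the list alone 12 were lower and 2 higher, and with the block 11 fell, including NR2E1 and ID1 (−1.93), while the growth factor gene FGF19 rose (2.30). Both sets were lower by camera, at Benjamini-Hochberg adjusted p = 5.79e-08 for ganglion cell genes (adjusted p = 0.186 with an estimated correlation) and 6.36e-10 for progenitor genes (adjusted p = 0.244 with an estimated correlation).

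Notch pathway genes, which keep progenitors from differentiating, had a median log2 fold change of −0.53 over 16 members, −0.85 and −0.48 within replicates 1 and 2. With the block 6 of them fell, among them DLL1 (−1.79), LFNG (−1.74), HES5 (−1.61) and HES1 (−1.60), and adjusted over the list alone 0 passed with group alone and 7 fell with the block. S phase genes had a median of −0.43 over 37 members and G2 and M phase genes −0.56 over 38. With the block the S phase genes RFC2 (−0.82) and POLA1 (−0.81) fell, and of the G2 and M phase genes 4 fell and CKS2 (2.88) and CKS1B (1.63) rose. Within replicates 1 and 2 the medians were −0.66 and −0.30 for S phase and −0.25 and −0.75 for G2 and M phase. Adjusted over the list alone neither cell cycle list held a call with group alone, while with the block 12 S phase genes were lower and of the G2 and M phase genes 2 were higher and 16 lower. All 3 sets were lower by camera, at Benjamini-Hochberg adjusted p = 0.000119, 1.69e-05 and 4.56e-05 (adjusted p = 0.530 with an estimated correlation for each). With equal numbers of cells per class the median became 0.28 for S phase and −0.058 for G2 and M phase genes, and was −0.57 for Notch pathway genes.

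Thyroid hormone pathway genes had a median log2 fold change of 0.61 over 10 members, 0.89 and 0.30 within replicates 1 and 2, and 0.42 with equal numbers of cells per class. RXRG alone rose with group alone, 4 were higher when adjusted over the list alone, and with the block RXRG, THRB, the activating deiodinase DIO2 (2.97) and the coactivator NCOA1 (0.95) rose and 1 fell. The set was higher (camera, Benjamini-Hochberg adjusted p = 1.62e-06, and adjusted p = 0.186 with an estimated correlation). Stress genes were lower as a set, with a median of −0.41 over 13 members, −0.36 and −0.23 within replicates 1 and 2 (camera, Benjamini-Hochberg adjusted p = 0.00982, and adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone 2 stress genes were lower, and with the block EGR1 (−1.82), JUN (−1.23), FOS (−0.93) and ATF3 (−0.79), all immediate early or stress-response factors, fell. The stress set lost its call without ThrbNeg replicate 1 (adjusted p = 0.0732), and its median became 0.14 with equal numbers of cells per class. Mitochondrial encoded genes had a median of 0.33 over 13 members, 0.35 and 0.27 within replicates 1 and 2, and 0 calls when adjusted over the list alone. That set was higher with group alone (camera, Benjamini-Hochberg adjusted p = 0.0431, adjusted p = 0.582 with an estimated correlation) and not with the block (adjusted p = 0.126). It also lost its call without ThrbPos replicate 2 (adjusted p = 0.361) and without ThrbNeg replicate 1 (adjusted p = 0.468), where its mean difference from the other genes was −0.10 on the log2 scale, and its median became −0.0058 with equal numbers of cells per class.

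The other 6 lists were not called. Neurogenic factors had a median log2 fold change of 0.54 over 10 members (camera, Benjamini-Hochberg adjusted p = 0.330), and adjusted over the list alone 3 were higher and 3 lower. Over the 7 classes, which leave out neurogenic progenitor-like cells, their median was 0.84 with all cells and −0.86 with equal numbers of cells per class. With the block NEUROD1 and SOX4 (1.39) were among 4 that rose, and GADD45G (−1.40) among 3 that fell. Without ThrbPos replicate 1 that list was called higher (adjusted p = 1.46e-10). Retinoic acid pathway genes had a median of −0.93 and a mean of −0.25 over 8 members while the set test pointed up (camera, Benjamini-Hochberg adjusted p = 0.937), and it pointed down with the block (adjusted p = 0.404). With equal numbers of cells per class its median became 0.045. Adjusted over the list alone RBP4 was higher and 1 member lower, and with the block ALDH1A3 (−1.76) and RARB (−1.40) fell. p53 and apoptosis genes had a median of 0.21 over 8 members (camera, Benjamini-Hochberg adjusted p = 0.0987), with 2 higher when adjusted over the list alone, and with the block TP53INP1 (1.31) and BCL2L1 (1.05) rose. Without ThrbNeg replicate 1 this list too was called higher (adjusted p = 0.0289). Synapse and neuron structure genes had a median of −0.27 over 12 members (camera, Benjamini-Hochberg adjusted p = 0.195), with 3 higher and 4 lower when adjusted over the list alone and 2 and 3 with the block. Glycolysis genes had a median of 0.13 over 17 members (camera, Benjamini-Hochberg adjusted p = 0.937), with 1 higher and 2 lower when adjusted over the list alone, and with the block the glucose transporter gene SLC2A1 (−1.70) fell and HK2 (1.69) rose. Interferon and DNA sensing genes had a median of −0.38 over 12 members (camera, Benjamini-Hochberg adjusted p = 0.709) and 0 calls when adjusted over the list alone or with the block. Their call depended on which library was left out, with adjusted p = 0.0241 lower without ThrbPos replicate 2, 0.000350 lower without ThrbNeg replicate 1 and 0.00302 higher without ThrbNeg replicate 2.

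**Figure D1:**
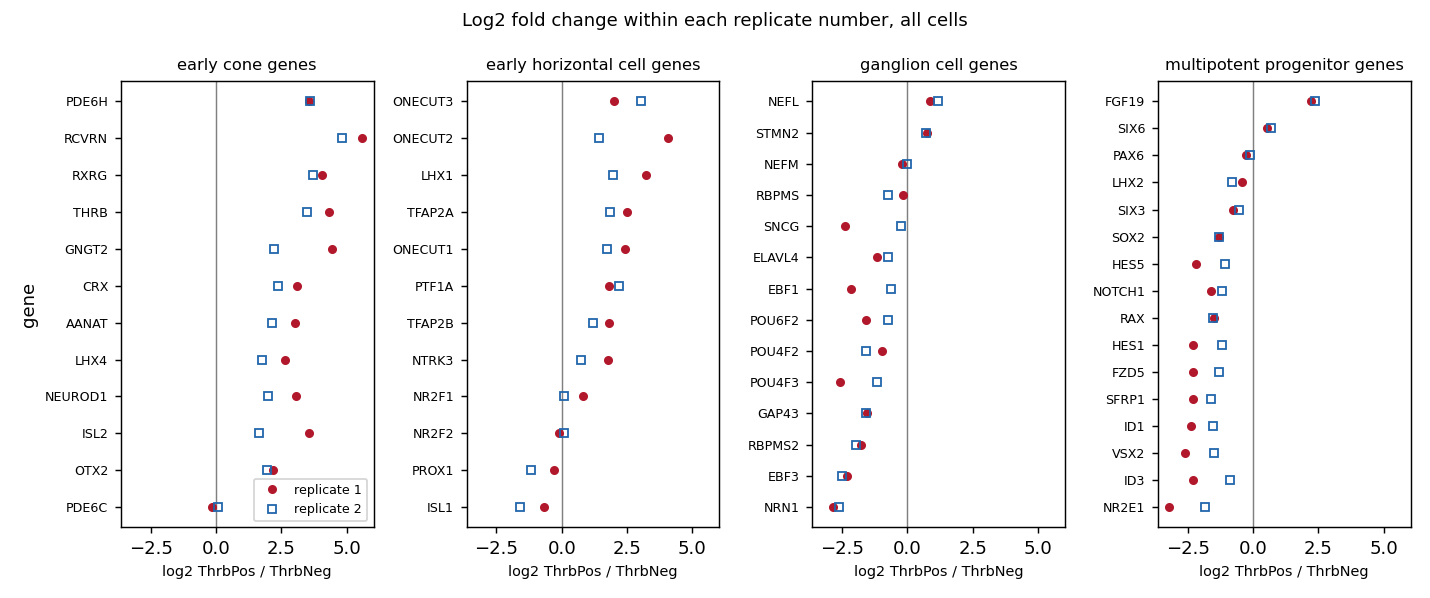
Log2 fold change of ThrbPos over ThrbNeg within each replicate for tested members of the early cone, early horizontal cell, ganglion cell and multipotent progenitor lists. In the fit with all libraries the list median was highest for early cone genes, at 3.15. It was lowest for multipotent progenitor genes, at −1.43.

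The second comparison asked how the makeup of cell classes differed. Photoreceptor-like cells made up 42.5% ± 6.19 (SD, n = 2) of ThrbPos and 8.31% ± 1.23 of ThrbNeg cells. Horizontal cell-like cells made up 7.17% ± 2.45 and 2.73% ± 0.501. Progenitor-like cells made up 7.98% ± 7.83 of ThrbPos and 38.5% ± 7.96 of ThrbNeg, neurogenic progenitor-like cells 2.55% ± 1.51 and 10.6% ± 0.817, and retinal ganglion cell-like cells 1.97% ± 0.448 and 8.32% ± 0.101. Cluster 2, in which horizontal and amacrine cell markers (TFAP2A, TFAP2B and PTF1A) were tied, made up 12.1% ± 4.2 and 4.90% ± 0.770. Horizontal and amacrine cell markers were tied as well in cluster 11, which held 86.0% of ThrbPos and 76.4% of ThrbNeg horizontal cell-like cells. Within replicate 1, photoreceptor-like cells were 38.1% (35.3 to 41.0%) of ThrbPos and 9.19% (8.20 to 10.2%) of ThrbNeg, and within replicate 2 they were 46.9% (45.9 to 47.9%) and 7.44% (6.71 to 8.23%).

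None of the 14 classes and clusters passed edgeR's quasi-likelihood test on cell numbers with group alone. The Benjamini-Hochberg adjusted p in that edgeR quasi-likelihood test was 0.121 for photoreceptor-like (log2 ratio 2.35), neurogenic progenitor-like (−2.03) and ganglion cell-like cells (−2.07), 0.147 for progenitor-like (−2.26), 0.214 for horizontal cell-like cells (1.39) and 0.216 for cluster 2 (1.31). With the replicate block the same edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 0.00156 for photoreceptor-like, 0.00307 for neurogenic progenitor-like, 0.00312 for ganglion cell-like, 0.00113 for progenitor-like, 0.0359 for horizontal cell-like cells and 0.0390 for cluster 2. The clusters were defined partly by genes that differed between the groups. Clustering without any listed gene gave 42.6% and 10.9% for photoreceptor-like, 8.10% and 37.6% for progenitor-like, 6.89% and 2.88% for horizontal cell-like and 1.48% and 7.42% for ganglion cell-like cells in ThrbPos and ThrbNeg. Differing genes outside the lists, such as IMPG2 and NANOS1, were not barred from it, so it does not remove that dependence. Whatever set the 2 labels, and the lower median depth of ThrbPos replicate 1, can shape these shares.

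**Figure D2:**
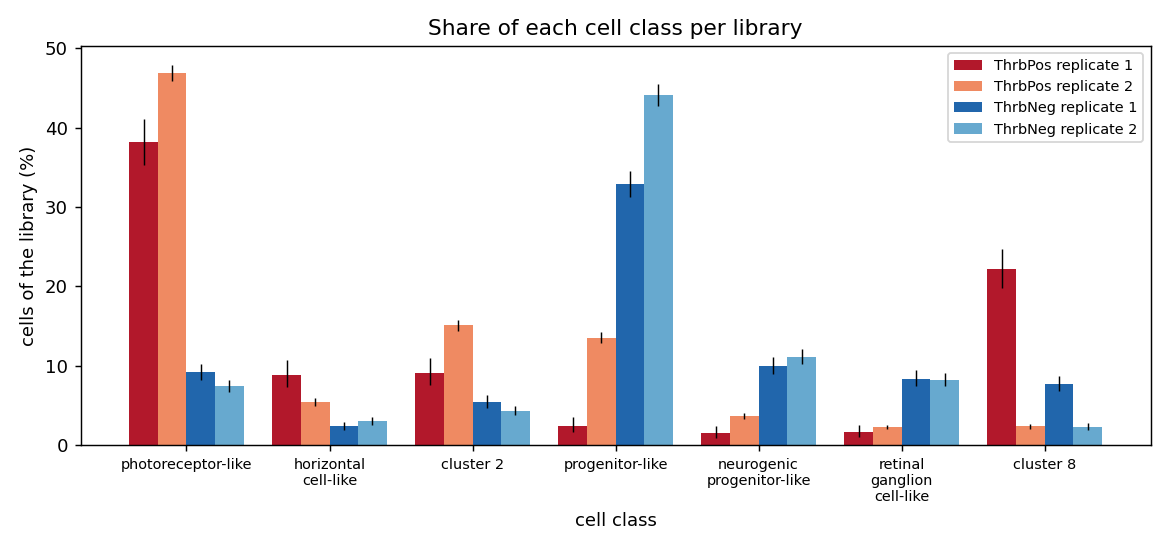
Percentage of cells per library in the photoreceptor-like, horizontal cell-like, progenitor-like, neurogenic progenitor-like and retinal ganglion cell-like classes and in clusters 2 and 8. Bars stand for the 4 libraries, with exact 95% intervals that cover counting error only. Photoreceptor-like cells make up 38.1% and 46.9% of the ThrbPos libraries and 9.19% and 7.44% of the ThrbNeg libraries.

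The third comparison looked within a class, so that a different mix of classes could not by itself set the result. A different mix of the clusters that make up a class still could, and these mixes differed between the groups, as given below. In horizontal cell-like cells 2 genes rose in ThrbPos. RBP4 stood at 607 ± 223 CPM (SD, n = 2) in ThrbPos and 44.1 ± 7.84 in ThrbNeg (log2 fold change 3.84, SE 0.41, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00362), with log2 fold changes of 3.0 and 4.06 within replicates 1 and 2. EGFP stood at 126 ± 45.2 CPM in ThrbPos and had 0 UMIs in the 75 and 145 ThrbNeg cells (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0420). In cluster 14, led by PTF1A, FGF19 and DLX1, RBP4 (log2 fold change 2.90), the ribosomal protein gene RPL31 (1.61) and FGF19 (1.15) rose, at Benjamini-Hochberg adjusted p = 0.00550, 0.0433 and 0.0433 in edgeR's quasi-likelihood test. RBP4 in horizontal cell-like cells was 3.91% and 7.01% of its level in photoreceptor-like cells of ThrbPos replicates 1 and 2. Free RNA from photoreceptor-like cells could not be told apart from a rise of RBP4 within the class. With the block the counts became 8 higher and 7 lower in horizontal cell-like cells, where the growth factor receptor gene FGFR3 (−2.34) and the GABA-synthesising enzyme gene GAD1 (−1.05) fell, and 17 and 8 in cluster 14. Without ThrbNeg replicate 2 horizontal cell-like cells had 0 calls, and without ThrbPos replicate 1 they had 30, without ThrbPos replicate 2 9 and without ThrbNeg replicate 1 34. Cluster 14 had 37, 17, 24 and 6 calls without ThrbPos replicates 1 and 2 and ThrbNeg replicates 1 and 2, with only 27 cells in ThrbPos replicate 1. Thinned to 1000 UMIs per cell, cluster 14 lost all 3 calls, at log2 fold changes of 2.69 for RBP4, 1.47 for RPL31 and 1.14 for FGF19, with 911 genes tested. Without the top 5% of doublet scores RPL31 and FGF19 there (adjusted p = 0.0780 for both) and EGFP in horizontal cell-like cells lost their calls, and RBP4 kept its call in both.

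In photoreceptor-like, progenitor-like and cluster 2 cells edgeR's quasi-likelihood test with group alone called 0 genes of 5934, 9147 and 3498 tested. At an unadjusted p under 0.05 the same edgeR test counted 450, 120 and 123 genes. In progenitor-like and cluster 2 cells that is under 5% of the genes tested, the share that no difference would give. DESeq2 called 36, 1 and 2 genes there, and with the block edgeR called 58 higher and 115 lower, 61 higher and 0 lower, and 5 higher and 0 lower. Among photoreceptor-like cells the block's largest falls in ThrbPos were the bipolar cell factor VSX1 (log2 fold change −4.14), AKAP12 (−3.36), SPON1 (−3.19), NFIB (−2.96) and the neuropeptide gene NPY (−2.94). Its largest rises there, besides EGFP, were RCVRN (2.91), TARBP2 (2.42), DNA2 (2.25), a nuclease of DNA replication, and CHTF8 (2.17), which acts in sister chromatid cohesion. OTX2 (0.08 with group alone) and ONECUT1 (−0.10) passed neither test within photoreceptor-like cells, while THRB (1.6) passed with the block. OTX2 and THRB are both on the marker list of this class. In progenitor-like cells RXRG (2.97), RBP4 (2.89), the neuroendocrine granule gene CHGA (2.18) and NEUROD1 (2.15) rose with the block. EGFP, OTX2, THRB and ONECUT1 rose there too (Benjamini-Hochberg adjusted p = 2.70e-23, 1.21e-07, 0.000955 and 0.00154 in edgeR's quasi-likelihood test with the block), though the last 3 overlapped between the groups' libraries, and within replicates 1 and 2 THRB had log2 fold changes of −1.84 and 1.88 and ONECUT1 −0.29 and 1.86. ThrbPos replicate 1 held only 28 progenitor-like cells. Its values for NEUROD1 (27.6 CPM), CHGA (41.3 CPM) and EGFP (55.1 CPM) in these cells rest on a few UMIs each. Left out 1 at a time in the order ThrbPos 1, ThrbPos 2, ThrbNeg 1 and ThrbNeg 2, the libraries left 99, 75, 0 and 0 calls in photoreceptor-like cells, 15, 0, 36 and 67 in progenitor-like cells and 20, 10, 11 and 0 in cluster 2.

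Lists within photoreceptor-like cells set cycling and early cone genes apart from progenitor genes. The medians were 1.27 for early cone genes, 1.00 for S phase genes and 0.71 for G2 and M phase genes, and −1.46 for multipotent progenitor genes, −0.84 for neurogenic factors and −0.72 for Notch pathway genes. By camera the first 3 sets were higher (Benjamini-Hochberg adjusted p = 2.00e-07, 4.36e-09 and 1.48e-11) and the last 3 lower (1.65e-14, 4.79e-08 and 3.58e-07). Adjusted p with an estimated correlation was 0.210 for progenitor genes and 0.330 for the others. The classes were not made of the same clusters in both groups: in replicates 1 and 2, cluster 1 held 18.8% and 36.7% of ThrbPos and 72.4% and 55.7% of ThrbNeg photoreceptor-like cells, cluster 6 held 4.35% and 19.6% against 2.76% and 3.71%, and cluster 13, with the mitotic genes CENPF and NUSAP1 among its leading genes, held 12.1% and 12.4% against 1.38% and 6.57%. Cluster 4 held 6 of 28 and 67.8% of ThrbPos and 5.01% and 29.8% of ThrbNeg progenitor-like cells. In progenitor-like cells early cone genes were higher, with a median of 2.46 (camera, Benjamini-Hochberg adjusted p = 8.84e-14), as were neurogenic factors (0.34, adjusted p = 0.000489), with adjusted p = 0.689 with an estimated correlation for both. Whether RNA from photoreceptor-like cells adds cone transcripts to progenitor-like cells was not tested. S phase genes (−0.21, adjusted p = 0.00407) and G2 and M phase genes (−0.33, adjusted p = 0.000171) were lower in progenitor-like cells (camera, Benjamini-Hochberg, and adjusted p = 0.766 with an estimated correlation). G2 and M phase genes were also lower in horizontal cell-like cells (−0.32, adjusted p = 0.00977, and adjusted p = 0.804 with an estimated correlation), thyroid hormone pathway genes higher in photoreceptor-like cells (0.23, adjusted p = 0.00313, and adjusted p = 0.330 with an estimated correlation), and synapse genes higher in cluster 14 (0.90, adjusted p = 0.000996, and adjusted p = 0.365 with an estimated correlation), all by camera with Benjamini-Hochberg adjustment. With the block further calls were gained for synapse genes in photoreceptor-like cells (adjusted p = 0.0438), and thyroid hormone pathway (0.0290) and synapse genes (0.0238) in progenitor-like cells. In the numbered clusters the block gained a call for Notch pathway genes in cluster 2 (adjusted p = 0.0175) and lost that for ganglion cell genes in cluster 14 (adjusted p = 0.0328 with group alone, adjusted p = 0.365 with an estimated correlation, and 0.0617 with the block). With group alone, adjusted p with an estimated correlation was 0.330 for the list gained in photoreceptor-like cells, 0.689 for both gained in progenitor-like cells and 0.765 for the one gained in cluster 2, and none was run with the block. Neurogenic progenitor-like and ganglion cell-like cells were not tested, with 17 and 19 cells in ThrbPos replicate 1.

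The fourth comparison followed the series title and asked how many cells held UMIs of OTX2, of ONECUT1 and of both. Cells were thinned to 1000 UMIs each, which left out shallower cells and kept 695 of 1146, 8276 of 9686, 2499 of 3157 and 4251 of 4702 cells of ThrbPos replicates 1 and 2 and ThrbNeg replicates 1 and 2. OTX2 was seen in 49.3% ± 1.32 (SD, n = 2) of ThrbPos and 16.5% ± 1.79 of ThrbNeg cells, ONECUT1 in 34.1% ± 2.22 and 10.5% ± 0.511, and both in 13.4% ± 0.175 and 3.20% ± 0.338. Without thinning the shares were 48.5% and 20.7% for OTX2, 37.3% and 14.7% for ONECUT1 and 18.4% and 5.67% for both. All 3 shares were separated between the groups, and the exact two-sided permutation test gave p = 0.33, the smallest that 2 against 2 libraries can give. Within replicate 1 both genes were seen in 13.2% (10.8 to 16%) of ThrbPos and 3.44% (2.76 to 4.23%) of ThrbNeg cells, and within replicate 2 in 13.5% (12.8 to 14.2%) and 2.96% (2.47 to 3.52%). If the genes had been seen independently of each other, 17.9% and 15.7% of cells in ThrbPos replicates 1 and 2 and 1.66% and 1.80% in ThrbNeg replicates 1 and 2 would have held both.

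Within the photoreceptor-like class the pooled shares were alike between the groups. Pooled over the libraries of a group, of which replicate 2 gave 4039 of the 4407 ThrbPos cells there, OTX2 was seen in 78.7% of ThrbPos and 78.6% of ThrbNeg cells, ONECUT1 in 29.3% and 28.6%, and both in 22.6% and 23.4%. Within replicate 1 the ThrbPos and ThrbNeg shares were 87.8% and 82.6% for OTX2, 25.3% and 29.6% for ONECUT1, and 22.3% and 24.9% for both. Within replicate 2 they were 77.9% and 75.3%, 29.7% and 27.8%, and 22.6% and 22.1%. The intervals of each pair overlapped. OTX2 is on the marker list of this class and was among the 10 leading genes of each of its clusters. Like shares of OTX2 there were therefore close to given in advance. Horizontal cell-like cells, pooled as above, held ONECUT1 in 85.9% of ThrbPos and 88.2% of ThrbNeg cells and OTX2 in 5.78% and 4.58%. Cluster 2 held ONECUT1 in 62.9% and 60.2% of cells of ThrbPos replicates 1 and 2 and in 40.5% and 40.0% of ThrbNeg replicates 1 and 2. Neurogenic progenitor-like cells held ONECUT1 in 2 of 15, 28.2%, 14.2% and 12.3%, and both in 1 of 15, 14.1%, 6.60% and 7.50% in the same order. Progenitor-like cells held OTX2 in 2 of 24 and in 38.4% of cells of ThrbPos replicates 1 and 2 and in 0.910% and 11.5% of ThrbNeg replicates 1 and 2, ONECUT1 in 0 of 24, 10.2%, 1.11% and 2.24%, and both in 0 of 24, 5.91%, 0.101% and 0.596% in that order. As a measure of background, cluster 7, led by FABP7 and CDK1 and given no class, was pooled in the same way. It held OTX2 in 6.30% of 238 ThrbPos and 0.971% of 206 ThrbNeg cells. ONECUT1 was seen there in 2.10% and 0 of them, which for 0 of 206 cells is an upper 95% bound of 1.77%. Median depths before thinning were 1530.5 and 1586.5 UMIs, against 1955.5 and 2248 in progenitor-like cells. Cluster 15, also without a class and with median depths of 2269 and 2193.5 UMIs, gave other values. It held OTX2 in 16.7% of 84 ThrbPos and 2.42% of 454 ThrbNeg cells and ONECUT1 in 3.57% and 0.441%. The background thus depends on the cluster taken.

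**Figure D3:**
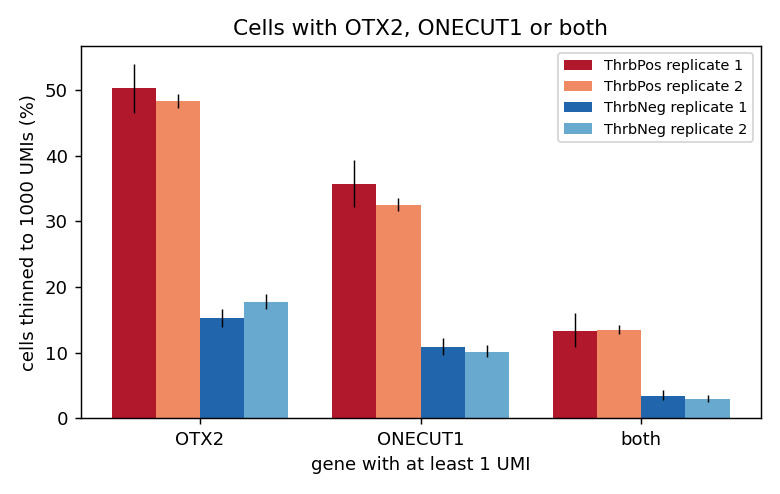
Percentage of cells with at least 1 UMI of OTX2, of ONECUT1 and of both per library, after thinning each cell to 1000 UMIs, with exact 95% intervals that cover counting error only. Both genes together were seen in 13.2% and 13.5% of the ThrbPos libraries' cells and in 3.44% and 2.96% of the ThrbNeg libraries' cells.

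The last comparison asked which genes went with both factors, with the library as a block and OTX2 and ONECUT1 themselves left out. In ThrbPos replicates 1 and 2 and ThrbNeg replicates 1 and 2, 82 of 92, 913 of 1116, 63 of 86 and 66 of 126 cells with both were photoreceptor-like. Of cells with ONECUT1 only, 11 of 156, 285 of 1577, 12 of 186 and 17 of 306 were, so this contrast also compares cell classes. Against cells with ONECUT1 only, cells with both carried more cone and fewer horizontal cell transcripts. RBP4 (log2 fold change 3.11), DIO2 (2.97), RXRG (2.69) and THRB (2.55) were higher, and TFAP2B (−4.58), TFAP2A (−4.22), FXYD6 (−4.06) and the glutamate receptor gene GRIA4 (−3.92) were lower. Of the lists' tested members, 4 of 5 early cone genes were higher and 6 of 7 early horizontal cell genes lower. In all, 230 genes were higher and 277 lower of 4526 by edgeR's quasi-likelihood test, each of the 8 genes named here going the same way in all 4 libraries, with Benjamini-Hochberg adjusted p from 9.73e-08 for TFAP2A to 0.00552 for DIO2. Without ThrbPos replicate 2 the total was 282 genes.

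Of cells with neither factor, 34 of 190, 609 of 2698, 32 of 1933 and 57 of 3191 were photoreceptor-like in the same order of libraries. Here too the contrast compares cell classes. Against cells with neither factor, 268 genes were higher and 220 lower in cells with both. RBP4 (3.46), B3GAT2 (3.04), FSCN2 (2.93), RXRG (2.91) and NEUROD1 (2.79) were the largest rises, and the defensin gene AvBD5 (−3.24), the differentiation inhibitor ID1 (−3.24), the fatty acid binding protein gene FABP7 (−3.08), S100A13 (−2.76) and METRN (−2.74) the largest falls. All 5 tested early cone genes and 11 of 13 mitochondrial encoded genes were higher, and 10 of 14 multipotent progenitor genes lower. Against cells with OTX2 only, edgeR's quasi-likelihood test called 0 of the 4526 genes, with 197 at an unadjusted p under 0.05, 17 calls without the filter on low counts, 2 calls without ThrbPos replicate 1 and 1 without ThrbPos replicate 2. RXRG and THRB there had log2 fold changes of 0.22 and 0.23, and the 7 early horizontal cell genes a median of 1.00 with 0 called. Within photoreceptor-like cells only, the calls against cells with OTX2 only, with ONECUT1 only and with neither numbered 3, 0 and 6 of 1238 genes. At 1000 UMIs a cell without a UMI of a factor may still express it, so these classes are classes of detection.

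Whether the effect of the label differed between classes was tested as an interaction against progenitor-like cells, which numbered only 28 in ThrbPos replicate 1. In photoreceptor-like cells 125 genes had an effect higher than in progenitor-like cells and 184 a lower one, of 9180. VSX1 (difference −3.88), ZNF804A (−3.76), the transcription factor TFAP2D (−3.04) and the scaffold protein gene AKAP12 (−2.98) were among those that went down most, and CHTF8 (3.38), the repair gene OGG1 (2.71), DNA2 (2.56), CDK2 (2.45) and CDC45 (2.32), the last 3 with parts in DNA replication or the cell cycle, went up most. Horizontal cell-like cells differed in 14 genes, with SCG3 (−2.63), CHGA (−2.18) and STMN2 (−1.58) lower and MCHERRY (2.18) higher. Cluster 2 differed in 46 genes and cluster 14 in 18. These are calls of edgeR's quasi-likelihood test with the library as a block. With ThrbPos replicates 1 and 2 and ThrbNeg replicates 1 and 2 left out in that order, the count became 677, 68, 15 and 77 in photoreceptor-like cells, 24, 4, 2 and 8 in horizontal cell-like cells, 246, 1, 1 and 13 in cluster 2, and 197, 1, 0 and 15 in cluster 14. The difference of ZNF804A was 3.43 without ThrbPos replicate 2. On simulated counts of photoreceptor-like and progenitor-like cells with the spread between libraries within a class, 65.3% of such calls were false, and 23.3 genes were called on average with nothing changed.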

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

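The test of horizontal cell genes in cells with both factors and both tests of free RNA for ONECUT1 were chosen only after the result was seen, the test of intervals after the ratio had missed its bound. The interaction tests were planned.

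The response to the label was set against that of progenitor-like cells. In photoreceptor-like cells 309 genes were called different, with VSX1, TFAP2D and AKAP12 lower and the replication genes DNA2 and CDC45 higher. Within replicates 1 and 2 CDC45 differed by 10.6 and 1.25, and DNA2 by 2.23 in both. The mix of clusters within photoreceptor-like cells also differed between the groups. Horizontal cell-like cells had 14 calls, cluster 2 had 46 and cluster 14 had 18. These counts came from edgeR's quasi-likelihood test of the interaction. Progenitor-like cells of ThrbPos replicate 1 numbered only 28, and on simulated counts of photoreceptor-like and progenitor-like cells at the wider spread between libraries 65.3% of such calls were false and 23.3 genes were called with nothing changed, more than the calls in horizontal cell-like cells or cluster 14. Without ThrbPos replicates 1 and 2 and ThrbNeg replicates 1 and 2, in that order, the calls numbered 677, 68, 15 and 77 in photoreceptor-like cells, 24, 4, 2 and 8 in horizontal cell-like cells, 246, 1, 1 and 13 in cluster 2 and 197, 1, 0 and 15 in cluster 14. These counts alone do not establish a different response.

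Among the transgenes and the genes named by the labels or the series title, OTX2 had a lower effect in photoreceptor-like than in progenitor-like cells. The log2 difference was −2.56, with −2.67 within replicate 1 and −1.84 within replicate 2. OTX2 was a marker of the photoreceptor-like class and a leading gene of each of its clusters. A small effect of OTX2 within that class was thus close to given in advance. ONECUT1 had a lower effect in photoreceptor-like cells (−1.91), horizontal cell-like cells (−2.03) and cluster 2 (−1.40). MCHERRY had a higher one in photoreceptor-like cells (1.82) and horizontal cell-like cells (2.18), with both replicates on the same side. For ONECUT1 the replicates went opposite ways, at 0.02, 0.78 and 1.5 within replicate 1 and −1.82, −2.08 and −1.48 within replicate 2 for photoreceptor-like, horizontal cell-like and cluster 2 cells, and without ThrbPos replicate 2 the differences were 0.44, 0.92 and 1.56. Of the progenitor-like cells, cluster 4 held 6 of 28 and 67.8% in ThrbPos replicates 1 and 2 and 5.01% and 29.8% in ThrbNeg replicates 1 and 2, so the libraries compared hold different mixes of these cells.

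OTX2 and ONECUT1 UMIs in the same cell could come from 2 cells caught in 1 droplet. Such cells would hold horizontal cell genes about midway between cells with either factor alone, but the highest median fraction over the libraries was 0.162, and the ratio of their median UMIs to the mean of the others was at most 1.04. Both values argue against doublets as the whole source. Free RNA as the only source of ONECUT1 would give both classes of a library a like share at equal depth. At 1000 UMIs per cell ONECUT1 was seen in 25.3% of photoreceptor-like cells and 0 of 24 progenitor-like cells of ThrbPos replicate 1, in 29.7% and 10.2% in ThrbPos replicate 2, 29.6% and 1.11% in ThrbNeg replicate 1, and 27.8% and 2.24% in ThrbNeg replicate 2. The 95% intervals lay at least 6.66 percentage points apart in each of the 4 libraries, which argues against free RNA as the only source. That free RNA adds part of these UMIs stays open: the ratio of the shares was 2.91 in ThrbPos replicate 2, just under the bound of 3 set for excluding it. A biological difference between the groups stays open and untested.

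RBP4 was higher in ThrbPos in classes other than photoreceptor-like cells, where free RNA from photoreceptor-like cells may add to it. From free RNA alone, RBP4 in horizontal cell-like cells would stand to its photoreceptor-like level as other early cone genes do. The quotient of the 2 was 5.87 in horizontal cell-like cells of ThrbPos replicate 1 and 1.38 in replicate 2. In cluster 2 it was 1.16 and 1.39. The 5.87 divides by a median of only 0.666% of the photoreceptor-like level over 6 cone genes, so the libraries do not decide. RBP4 stood at 607 and 44.1 CPM in ThrbPos and ThrbNeg horizontal cell-like cells, and at 557 and 44.7 in cluster 2. It was 512 and 70.3 in cluster 14, and 1273 and 188 in progenitor-like cells. Like levels in the first 3 of these are what free RNA would give, but do not exclude a change within the cells. A change within horizontal cell-like cells and RNA from photoreceptor-like cells cannot be told apart here.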

How the results depend on the processing

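Leaving out cells under 1000 UMIs, clusters 7, 8 and 21 or the top 5% of doublet scores, clustering without listed genes, keeping all cells of the classes used for the equal draw, and taking photoreceptor-like cells alone were chosen after the data were seen, and the other alternatives before. For the cases in which a call or direction changed, the cause was not tested unless given.

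Over all cells and within classes, 1469 of the values recomputed kept their direction and side of the threshold, 387 gained a call, 46 lost one and 31 turned. For class shares 145 kept both, 13 gained a call and 5 turned. For gene lists 152 kept both, 4 gained a call, 29 lost one and 5 turned. For differences between classes the numbers were 183, 10, 70 and 16, and for genes by detection 296, 6, 16 and 7. Of the shares of cells with OTX2 and ONECUT1, 18 moved by less than the spread between replicates and 6 by more. By the direction of the set test itself, which was the first measure used for lists and was replaced by the mean difference after the turned lists had been seen, 11 directions changed over 10 settings: retinoic acid genes in 5, glycolysis in 4 and interferon genes in 2.

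With the replicate block 713 genes were higher and 621 lower over all cells, and the counts were 25 in cluster 14, 5 in cluster 2, 15 in horizontal cell-like, 173 in photoreceptor-like and 61 in progenitor-like cells. The block also called the shares of progenitor-like (−2.66), neurogenic progenitor-like (−2.13), photoreceptor-like (2.36), horizontal cell-like (1.35) and ganglion cell-like cells (−2.07). The DESeq2 test called 249 genes higher and 210 lower over all cells, 2 in cluster 2, 1 in horizontal cell-like, 36 in photoreceptor-like and 1 in progenitor-like cells. DESeq2 size factors gave 5 calls in cluster 14. With no low-count filter, where the prior degrees of freedom rose from 3.71 to infinite, 529 genes were higher and 411 lower, with 21 in cluster 14, 31 in cluster 2, 19 in horizontal cell-like, 191 in photoreceptor-like and 78 in progenitor-like cells, 17 between cells with both factors and with OTX2 only, and a difference of 0.043 for THRB in cluster 2. Thinned to 1000 UMIs per cell, 11 genes were higher and 1 lower, with 0 in cluster 14, 1 in cluster 2, 1 in horizontal cell-like and 16 in progenitor-like cells. With only cells of at least 1000 UMIs 9 genes were higher, and without clusters 7, 8 and 21 0 were, by edgeR, and the glycolysis mean difference was −0.016.

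Equal cells per class were drawn from the 7 classes and clusters with at least 20 cells in every library, so neurogenic progenitor-like and ganglion cell-like cells and clusters 15, 19, 20, 21 and 25 were left out whole. Keeping all cells of these 7 classes, with 10806 genes tested, already gave 0 genes higher by edgeR, and turned ISLR2 (0.91) and ELAVL4 (0.091). List medians there were 3.01 for early cone, 1.57 for early horizontal cell, −0.021 for ganglion cell, −1.78 for multipotent progenitor and −0.55 for S phase genes, and 0.49 for synapse genes, which had −0.27 over all cells. Drawing equal numbers from the 7, which left 721 cells per library and 7167 genes tested, also gave 0 genes higher by edgeR. The log2 fold change in that draw was −0.23 for GADD45A, 0.24 for PCNA, 0.31 for UHRF1, 0.14 for HSPA8, −0.22 for COX1, 0.77 for ISLR2, −0.60 for TFAP2B, 0.28 for POLA1 and 0.61 for ATF3, each opposite in sign to its value over all cells. The lists' calls all ended with an estimated correlation, at 0 higher and 0 lower, and with fry, also at 0 and 0, with a smallest adjusted p of 0.0591. TMM on cell numbers gave cluster 19 a log2 ratio of 0.18. At the lower resolution the shares of neurogenic progenitor-like (−2.17), photoreceptor-like (2.34) and ganglion cell-like cells (−2.04) were called (adjusted p = 0.0437).

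Without the top 5% of doublet scores 1 gene each was called in cluster 14, cluster 2 and horizontal cell-like cells, and cells with both factors differed by 9.76 percentage points. With at least 2 UMIs the differences were 24 points for OTX2, 11.9 for ONECUT1 and 1.86 for both, and not thinned they were 27.9 for OTX2 and 12.7 for both. Not thinned, 1368 and 1299 genes were called between cells with both factors and with ONECUT1 only or neither. In ThrbPos libraries only, RXRG against OTX2 only was −0.22 and the count against neither was 294. In photoreceptor-like cells only, with fewer cells and 1238 genes, the counts were 3 against OTX2 only (RXRG −0.032), 0 against ONECUT1 only (EGFP −0.31) and 6 against neither.

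Leaving out 1 library at a time, where the lone library left in a group is assumed to vary like the other group, the genes called over all cells ranged from 0 to 96 higher and 0 to 31 lower. Log2 fold changes ranged from −2.19 to 1.32 for OASL, −4.04 to 2.80 for IFI6, −0.078 to 0.32 for COX1, −0.73 to 3.81 for CKS1B, −0.33 to 0.30 for NR2F2, −0.55 to 0.39 for CCNG1, −0.016 to 0.17 for HSP90AA1 and −0.11 to 0.64 for GAPDH. Mean differences ranged from −0.26 to 0.38 for glycolysis, −0.10 to 0.40 for mitochondrial encoded genes and −2.24 to 1.34 for interferon genes. Calls within classes ranged from 6 to 37 in cluster 14, 0 to 20 in cluster 2, 0 to 34 in horizontal cell-like, 0 to 99 in photoreceptor-like and 0 to 67 in progenitor-like cells. MCHERRY ranged from −0.0086 to 1.5 in cluster 2 and −0.44 to 0.72 in progenitor-like cells. ONECUT1 ranged from −0.11 to 0.41 in horizontal cell-like, −0.24 to 0.053 in photoreceptor-like and −0.60 to 2.14 in progenitor-like cells. OTX2 ranged from −0.066 to 0.25 in photoreceptor-like and THRB from −6.98 to 3.85 in progenitor-like cells.

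Leave-one-out ranges of the differences from progenitor-like cells were 0 to 197 genes in cluster 14, with ONECUT1 −1.03 to 1.90, NFASC −3.42 to 0.15, TFAP2D −3.83 to 0.077 and THRB −2.11 to 6.75. In cluster 2 they were 1 to 246 genes, with ONECUT1 −1.60 to 1.56, OTX2 −2.20 to 1.65, SRRM3 −4.96 to 3.63, SCG3 −3.53 to 0.14 and THRB −0.24 to 2.76. In horizontal cell-like cells they were 2 to 24 genes, with ONECUT1 −2.19 to 0.92, and in photoreceptor-like cells 15 to 677 genes, with ONECUT1 −2.15 to 0.44, THRB −1.31 to 7.63 and ZNF804A −5.52 to 3.43. Against OTX2 only the range was 0 to 2 genes, with EGFP −0.19 to 0.17 and RXRG −0.035 to 0.42. Against ONECUT1 only it was 282 to 589 genes, with EGFP −0.014 to 0.55, and against neither EGFP was −0.40 to 0.75. Log2 ratios of shares ranged from −0.88 to 2.03 for cluster 7, −1.06 to 2.42 for cluster 8 and −4.43 to 1.79 for cluster 19.

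Depth limits what a cell shows: at 1000 UMIs a factor without a UMI may still be expressed, and asking for 2 UMIs took the difference in cells with both factors to 1.86 points.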

Other observations

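The test of interferon genes between batches was chosen after the result was seen. The clusters below were looked at after the data were seen, and the test of the cells behind the interferon genes was set before its result was seen.

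Several clusters outside the named classes were looked at by their leading genes, some of which, such as AvBD5 and NR2E1, also led progenitor-like clusters. Cluster 15 was led by the retinoid enzymes RDH10 and ALDH1A3 with BMPR1B and CHRDL1, and made up 0.0873%, 0.878%, 2.09% and 8.40% of ThrbPos replicates 1 and 2 and ThrbNeg replicates 1 and 2. Cluster 20 was led by the defensin gene AvBD5, NR2E1 and ID3, had a median of 3973 UMIs and made up 0.262%, 0.0929%, 6.18% and 1.91% of the libraries in the same order. With the replicate block both had lower shares in ThrbPos (adjusted p = 0.000449 and 0.000123 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and with group alone neither passed (0.121 and 0.0990). At the lower resolution neither was a cluster of its own. Progenitor-like cells there made up 8.63% of ThrbPos and 47.7% of ThrbNeg, against 7.98% and 38.5% at resolution 1. Clusters 15 and 20 may thus be part of that class. Cells of cluster 20 also held a median of 2.14 times the median UMIs of their library, so doublets there stay open. Cluster 21, led by EPHA4 and KLHL4, was also lower in ThrbPos with the block only (0.00270 against 0.121).

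Photoreceptor-like cells held several kinds. Cluster 13 was led by RBP4 with the mitotic genes CENPF and NUSAP1 and made up 4.62%, 5.81%, 0.127% and 0.489% of the libraries, and cluster 6, with NANOS1, DIO2 and CBLN2, 1.66%, 9.19%, 0.253% and 0.276%. Cluster 18 carried IMPG1, RELN, TRHDE and CA10. VSX1, low in ThrbPos photoreceptor-like cells, led cluster 10 of the neurogenic progenitor-like class together with OLIG2 and NEUROG1, at 1.05%, 1.07%, 7.63% and 8.19%. Progenitor-like cluster 4, with SOX21 and NEUROG2, made up 0.524%, 9.16%, 1.65% and 13.1%, higher in replicate 2 of both groups and lower in ThrbPos within both replicates. Cluster 8, with a median of 385.5 UMIs, held 22.2% of ThrbPos replicate 1 and 2.40%, 7.70% and 2.28% of the others.

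Interferon genes were higher in replicate 2 of both groups, which may come from a difference between the batches. The median log2 difference of replicate 2 minus replicate 1 over the list was 1.26 in ThrbPos and 1.67 in ThrbNeg. Clusters 19 and 25, led by IFI6, IFIT5, OASL and RSAD2, held 64.6% of the list's UMIs in ThrbPos replicate 2 and 69.7% in ThrbNeg replicate 2. Because interferon genes lead these clusters, a large share there was close to given in advance. The difference between replicates was not recomputed without these clusters, so their part in it is not known. With 1 pair of libraries per batch a batch effect and a biological difference between the replicates stay open.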
